A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

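Total RNA from wild-type and H3 K4,79R yeast, 3 samples each, was extracted with hot acid phenol and about 20 micrograms per sample were made into biotin-labelled cRNA for Affymetrix yeast arrays, per the labels' protocols. Cells were taken at an optical density at 600 nm of 0.5 to 0.7. The deposited values are array intensity on a linear scale, 1 value per probe set and array. The submitters' processing notes name MAS5 for them, with no version. The deposited intensity values of the 3 wild-type arrays have 1 decimal and a 2%-trimmed mean of 125 each. On every mutant array all deposited values were whole multiples of 0.1 of a constant (tolerance 0.001 of that unit), so each is a signal of the same scale multiplied by the authors with 1 further constant: 0.922, 1.09 and 1.11 for arrays 1, 2 and 3. The basis of these constants is not given in the sources used here. Bacterial poly(A) control transcripts on the arrays gave a ratio of wild-type to mutant signal, after the constants were divided out, of 0.936, 1.06 and 1.08 for the pairs with the same number (geometric mean over 15 control probe sets). Scanner files and detection calls were not used here.

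How the arrays were scaled affects the direction of small changes, since a common factor shifts every gene of an array. By a rule fixed before the data were examined, arrays were to be rescaled only if their trimmed means differed by over 1.2-fold. The highest was 138.4 and the lowest 115.4, just within this limit, so the values were used as deposited. Quantile normalization, a common median and division by the constants were run as alternatives.

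The 9335 probe sets include 60 controls, which were left out. Of the other 9275, 6504 had 1 listed gene, 328 had several and 2443 had none. All 6504 single genes were found in the RefSeq gene table of assembly R64, which also updated symbols. An offset of 3.605, which is 0.1 of the median of the array medians of 36.05, was added to each signal before taking log2. Fold changes are on this log2(signal + offset) scale and understate the change of genes with a low signal. The 20% of probe sets with the lowest mean were left out, leaving 7420, of which 5913 had 1 gene. A gene with several probe sets was taken from the one with the highest mean, giving 5385 genes. Of 260 genes with several probe sets, 17 had a called one and 3 of these another of the opposite sign. The name suffixes s, x, i, f, g and r were grouped as marking shared probes, and their separate meanings were not told apart. Probe sets so named cover 263 of the tested genes and 27 of the called ones, which are named as uncertain.

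Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with 4 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 changes are mutant minus wild type and carry the moderated SE; signals are means ± SD of 3 arrays. An exact permutation test of 3 against 3 arrays cannot go below 0.1, so none is given for single genes. In a simulated comparison of 3 against 3 arrays over the 5385 genes, the fit recovered 28% of 50 genes changed 1.5-fold, 80% at 2-fold, 98% at 4-fold and 98% at 8-fold. None had the wrong sign, and 6.75% of its calls were unchanged genes. The simulation changed 200 genes and had no errors shared between the genes of an array. These rates are thus a check on uncorrelated genes only and may not hold for the real arrays. Probe sets with several genes, or none, were fitted in the same way over all 7420 probe sets, where adjusted p-values differ slightly from those of the fit by gene.

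The 38 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. On simulated data camera called none of 100 random lists at an unadjusted p under 0.05, a check on unchanged, uncorrelated genes only. The share of called genes near chromosome ends was compared with Fisher's exact test. The plan was to use 20 kb from the ends, with 10 and 30 kb as alternatives. No distances in kb were used, because the sources used here name no genome build for the array. Gene positions were at hand in the RefSeq table, so this was a choice and not forced by a lack of positions. Gene order, and whether neighbouring genes overlap, came from the gene positions in the RefSeq table. The 10 outermost protein-coding genes of each of 32 chromosome ends in the RefSeq order, 320 genes with 176 tested, took the place of 20 kb, and 5 and 15 genes that of 10 and 30 kb. The planned tests in kb were not run, and 5227 tested genes had a place in the order.

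The genes named follow a rule fixed beforehand: the 12 called genes with the largest rise and the 12 with the largest fall among those whose mutant values all lay beyond the wild-type values; H3, SET1, DOT1, SIR and silent locus genes; up to 4 called members per list, or the 2 with the smallest p; and the 6 called genes with the largest change near chromosome ends. Genes named outside it are marked where they occur. Alternatives covered the offset, the filter, the scaling, the replicate number as a block, the variance model, the probe set per gene, the threshold and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.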

Results

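The 6 arrays measured mRNA levels in budding yeast, 3 from wild-type cells and 3 from cells carrying histone H3 with lysines 4 and 79 replaced by arginine, called K4,79R below. Both residues are methylated in wild-type chromatin, lysine 4 by Set1 and lysine 79 by Dot1, and arginine at these places cannot be methylated. The stated purpose was to find genes whose mRNA level differs between the mutant and the wild type. Cells were grown in rich glucose medium and taken in mid-logarithmic growth. The labels do not say whether the 3 samples of a group came from separate cultures. Each p-value of a single gene thus measures only the spread between these samples, which may be technical. Tests of lists and of chromosome ends rest on the same samples. The number of arrays limits the precision of every value.

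The median signal was 36.8, 35.3 and 34.1 on wild-type arrays 1, 2 and 3, and 31.8, 42.9 and 40.1 on mutant arrays 1, 2 and 3. Mutant array 1 stood apart from the other mutant arrays: its correlation across probe sets, which are not independent replicates, was 0.969 with mutant array 2 and 0.976 with mutant array 3, against 0.990 between those arrays and 0.984 to 0.993 among the wild-type arrays. The 3′ to 5′ signal ratio of ACT1, a measure of transcript integrity, was 1.00 on mutant array 1 and between 1.498 and 1.64 on the other 5 arrays. The same ratio of SPT15 was 5.71 on mutant array 1, 2.79 on mutant array 2, 3.35 on mutant array 3 and between 5.02 and 6.15 on the wild-type arrays.

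Histone H3 itself is encoded by HHT1 and HHT2, whose products are identical, and every probe set for them is listed under both genes. The brightest read 4864 ± 682 (SD, n = 3) in wild type and 4290 ± 664 in the mutant, a log2 difference of -0.18 ± 0.17 (SE) that did not pass the test (limma adjusted p = 0.569). Another read 422 ± 12.2 in wild type and 245 ± 95.5 in the mutant, a log2 difference of -0.86 ± 0.28 with an adjusted p of 0.142. This second value passed the threshold without mutant array 1, at -0.50, with quantile normalization, at -0.92, and with a common median, at -0.96. The third lay near background, at 7.57 ± 1.56 and 6.38 ± 2.94. The substitution changes codons and not the probes' targets as a whole, so these levels do not check the labels. Neither SET1, at -0.11 ± 0.21, nor DOT1, at 0.00 ± 0.21, was called, and the sign of each depended on which array was left out.

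Of 5385 genes tested, 150 had a higher and 78 a lower mRNA level in the mutant at an adjusted p under 0.05. All 228 had their 3 mutant values beyond all 3 wild-type values. A call with 3 against 3 arrays makes such separation likely, so it adds no separate support. Such separation was seen for 28.8% of all tested genes, against 10% by chance. A change of at least 2-fold was reached by 48 of the higher and 13 of the lower genes. The balance of directions depended on the scaling between arrays: 65.8% of the called genes were higher as deposited, 52.6% (182 higher, 164 lower) with the constants on the mutant arrays divided out, 49.1% (181 and 188) with quantile normalization and 42.9% (156 and 208) with a common median. Leaving out wild-type array 1, 2 or 3 left 22, 23 or 65 called genes, leaving out mutant array 2 or 3 left 51 or 47, and leaving out mutant array 1 gave 1120.

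The largest rise was that of FLO1 (YAR050W), a cell-surface lectin that makes cells flocculate. Its signal was 32.5 ± 7.98 (SD, n = 3) in wild type and 195 ± 20.1 in the mutant, 5.57-fold (log2 2.48 ± 0.18 SE, adjusted p = 0.00206). This probe set carries one of the suffixes grouped here as shared probes, so the value is uncertain as a measure of FLO1 alone. THI4 (YGR144W), needed to make the thiazole part of thiamine, rose 3.63-fold from 59.0 ± 9.05 to 223 ± 12.9. ECM13 (YBL043W) rose 3.46-fold and the stress gene DDR2 (YOL052C-A) 2.84-fold. SNO1 (YMR095C), which acts in vitamin B6 synthesis, rose 2.76-fold from a low signal of 10 ± 1.97 to 33.7 ± 2.06. The other 7 of the 12 largest rises lay between 2.58-fold and 2.66-fold: FMP33, the plasma-membrane heat shock gene HSP30, YNR064C, the cardiolipin phospholipase gene CLD1, the cell wall gene PIR3, the pyruvate decarboxylase gene PDC6 and ANS1.

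Falls were smaller. On the log2 scale with the offset COS9 (YKL219W) fell most, from 68.9 ± 7.25 to 26.9 ± 10.6, a log2 change of -1.31 ± 0.27 (adjusted p = 0.0367). COS10 and COS8, of the same family of genes near chromosome ends, changed by -1.17 and -1.14. COS10 fell between lower signals, from 20.0 to 6.94, where the offset understates the change. All 3 COS genes were read by probe sets with a suffix grouped here as shared probes. ATO3 (YDR384C), a putative ammonium exporter, fell from 341 ± 34.0 to 140 ± 20.6 (log2 -1.27 ± 0.14). HO (YDL227C), the endonuclease that starts mating-type switching, fell from 138 ± 21.4 to 55.6 ± 10.8 (log2 -1.27 ± 0.18). AIF1 (-1.21), UPA2 (-1.18), CDC50 (-1.17), which encodes a subunit of a lipid flippase, and the purine synthesis gene ADE8 (-1.11) followed. HUA1 (-1.09), YOR072W-B (-1.09, shared probes) and YNL040W (-1.02) completed the 12.

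Across all 24 genes and the further genes named for their lists, 74 were called. Without wild-type array 1, 2 or 3, 20, 19 and 34 of the 74 were called in the same direction, and without mutant array 1, 2 or 3, 74, 30 and 27. None turned its direction. Among all tested genes, 16 higher and 5 lower genes were called with all arrays and without each array in turn. Of these 21, 19 are named here: FLO1, THI4, ECM13, DDR2, SNO1, SNZ1, HSP30, HSP12, CLD1, PIR3, PST1, PDC6, PHO5 and HUG1 were higher, and ATO3, AIF1, UPA2, CDC50 and ADE8 lower.

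**Figure D1:**
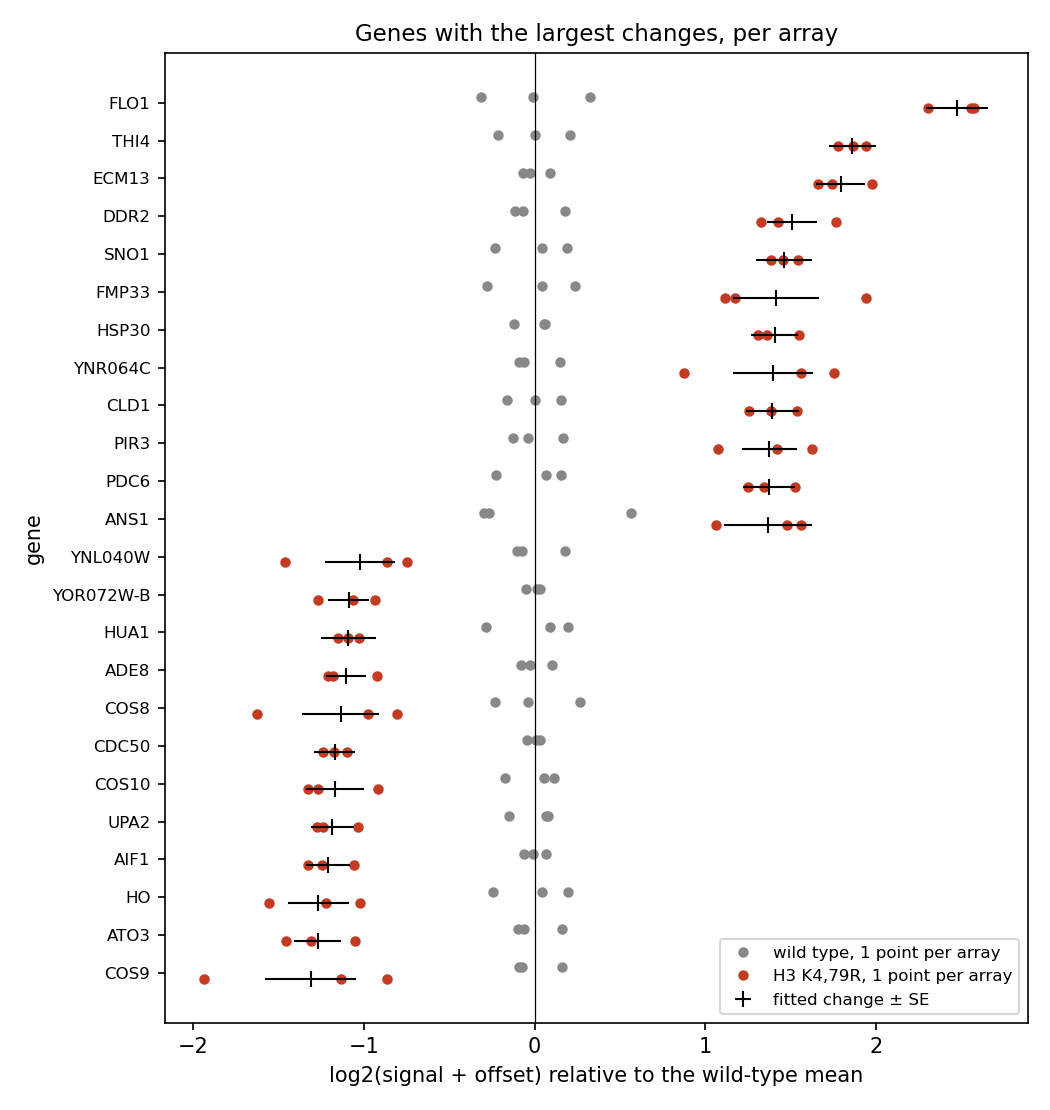
Signal of the 12 genes with the largest rise and the 12 with the largest fall, as log2(signal + offset) relative to the wild-type mean of each gene. Each point is 1 array, with 3 wild-type arrays in grey and 3 mutant arrays in red, and the black mark is the fitted change with its SE. Genes were chosen so that no mutant point overlaps the wild-type points of its gene. FLO1 lies farthest from 0 at 2.48.

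Gene lists fixed beforehand were tested as groups, and 12 of 38 were called with camera at its preset correlation between genes, 7 higher and 5 lower than the other genes. All 12 calls were lost when the correlation was estimated from the 6 arrays, which gave the highest adjusted p of any alternative run for each of the 12. The lowest p at the preset correlation was that of the genes induced in the environmental stress response, while the flocculation and COS lists below had larger mean changes and lower unadjusted p-values with an estimated correlation. Of its 49 tested members, 12 rose and none fell (22 and none adjusted over the list alone), and the mean log2 change was 0.42 (adjusted p = 6.05e-08, and adjusted p = 0.385 with an estimated correlation). HSP12, which encodes a small membrane-stabilising stress protein, rose 2.50-fold from 481 ± 42.6 to 1205 ± 43.8. DDR2, HSP30 and SPG4 rose 2.84-fold, 2.65-fold and 2.57-fold. Of the 27 heat shock and chaperone genes only the mitochondrial disaggregase gene HSP78 rose (1.76-fold), 2 rose adjusted over the list alone, and the list was not called (adjusted p = 0.512).

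Genes of respiration and of growth on carbon sources other than glucose stood higher in the mutant. Whether RNA quality contributed, given the differences between arrays in the SPT15 ratio, was not tested. Of 46 tested genes of the TCA cycle and respiration, 5 rose and none fell (17 and none adjusted over the list alone), with a mean log2 change of 0.32 (adjusted p = 9.70e-07, and adjusted p = 0.409 with an estimated correlation); fry also ended its call (adjusted p = 0.0573). They include the ATP synthase genes ATP4 (1.85-fold) and ATP14 (1.63-fold), QCR8 (1.71-fold) of complex III and SDH2 (1.56-fold) of succinate dehydrogenase. Second probe sets of ATP14 (log2 0.61) and QCR8 (0.41) were not called in the fit of all probe sets. There the first of ATP14 also missed the threshold (adjusted p = 0.0511). Of 20 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 4 rose and none fell (10 and none adjusted over the list alone), with a mean of 0.47 (adjusted p = 2.01e-05, and adjusted p = 0.409 with an estimated correlation). The thiolase gene POT1 rose 1.99-fold, malate synthase MLS1 1.87-fold, the acyl-CoA synthetase gene FAA2 1.71-fold and fructose-1,6-bisphosphatase FBP1 1.64-fold, all from low wild-type signals between 8.33 and 18.8.

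Sugar use showed changes in single genes. Among 21 genes of hexose transport and glucose repression, the transporter gene HXT5 rose 2.07-fold and HXT1, a low-affinity transporter gene induced by glucose, fell from 471 ± 37.0 to 274 ± 37.3. The list was not called (adjusted p = 0.584; 1 higher and 1 lower adjusted over the list alone). Of 21 genes of glycolysis and fermentation, PDC6 (2.59-fold), TDH1 (2.01-fold) and the glucose-repressed alcohol dehydrogenase gene ADH2 (1.99-fold) rose, while 4 rose and 2 fell adjusted over the list alone. That list was not called (adjusted p = 0.641), and its median of -0.01 and mean of 0.14 differ in sign. GAL4 was the only called member of 9 galactose genes (1.71-fold, 1 higher adjusted over the list alone, list adjusted p = 0.639). None of 7 maltose and other sugar genes was called over all genes (1 higher adjusted over the list alone; list adjusted p = 0.639), with MAL11 at 0.52 ± 0.14 and MAL33 at -0.27 ± 0.15.

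Cell-surface genes included both called and uncalled lists. All 6 tested flocculation genes had a positive change, 2 of them called (3 adjusted over the list alone), with a mean of 0.83 (adjusted p = 0.00106, and adjusted p = 0.385 with an estimated correlation). Besides FLO1, the mucin gene FLO11 rose 1.72-fold from 77.6 ± 5.45 to 138 ± 28.2. In the list of seripauperin (PAU) and anaerobic wall genes 1 of 17 rose, PAU23 at 1.70-fold (7 adjusted over the list alone), with a mean of 0.32 (adjusted p = 0.00698, and adjusted p = 0.409 with an estimated correlation). PAU23 was read by a probe set with shared probes, and without such probe sets the list lost its call (mean 0.22, adjusted p = 0.176). Of 43 cell wall integrity and wall protein genes 4 rose and none fell (7 and none adjusted over the list alone): PIR3 (2.59-fold), PST1 (2.01-fold), the glucan synthase gene GSC2 (1.82-fold) and the phosphatase gene PTP2 (1.62-fold). That list was not called (adjusted p = 0.148) but passed the threshold without mutant array 2 (adjusted p = 0.0133) and with quantile normalization (adjusted p = 0.0340). In the fit of all probe sets, other probe sets of GSC2 lay between 0.24 and 0.86 on the log2 scale, not all of them called. Those of PTP2 lay between 0.53 and 0.70, none of them called.

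The COS family, whose members lie near chromosome ends and encode membrane proteins, stood lower. Of 7 tested members, 4 fell and none rose (the same counts adjusted over the list alone), with a mean log2 change of -0.80 (adjusted p = 1.29e-04, and adjusted p = 0.385 with an estimated correlation). COS4 fell from 592 ± 33.4 to 300 ± 44.6 beside COS8, COS9 and COS10. All 4 were read by probe sets with a suffix grouped here as shared probes, and the list kept its call without such probe sets. A second probe set of COS9 gave -0.49 and others of COS10 gave -0.65 and -0.24, none of them called, while those of COS8 gave -1.32 and -1.02, both called, the first (adjusted p = 0.0344) on a probe set without the suffix for shared probes.

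Purine synthesis and ribosome genes stood slightly lower as lists. Of 19 genes of purine synthesis and one-carbon metabolism, 3 fell and none rose (5 lower and 1 higher adjusted over the list alone), with a mean of -0.18 (adjusted p = 0.0194, and adjusted p = 0.480 with an estimated correlation). ADE8 fell from 556 ± 37.1 to 257 ± 29.6, ADE2 from 1100 ± 22.1 to 679 ± 24.5 and the glycine cleavage gene GCV1 from 226 ± 18.5 to 147 ± 9.48. The list lost its call without mutant array 1 (mean -0.08, adjusted p = 0.0602), without wild-type array 3 (mean -0.16, adjusted p = 0.0508) and with fry (adjusted p = 0.103). Of 77 ribosome biogenesis genes 1 fell and none rose (none in either direction adjusted over the list alone), with a mean of -0.09 (adjusted p = 0.00164, and adjusted p = 0.814 with an estimated correlation). The called gene, UTP22, had 5 further probe sets between -0.81 and 0.14, which disagreed in sign, and fry ended the call of the list (adjusted p = 0.406).

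None of 81 cytosolic ribosomal protein genes was called in limma, where 1193 of the 5385 genes had an unadjusted p under 0.05, and their mean was -0.06 (adjusted p = 0.0222, and adjusted p = 0.871 with an estimated correlation). RPS1B was at -0.44 ± 0.13 and RPP1, which the name rule took in although it encodes a subunit of RNase P, at -0.33 ± 0.11. This list lost its call without wild-type array 3 (mean -0.02, adjusted p = 0.321) and without mutant array 2 (mean -0.01, adjusted p = 0.726). It also lost it with quantile normalization (mean -0.03, adjusted p = 0.542), with a common median (mean -0.16, adjusted p = 0.119), without the lowest 40% of probe sets (adjusted p = 0.0796) and with fry (adjusted p = 0.649).

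**Figure D2:**
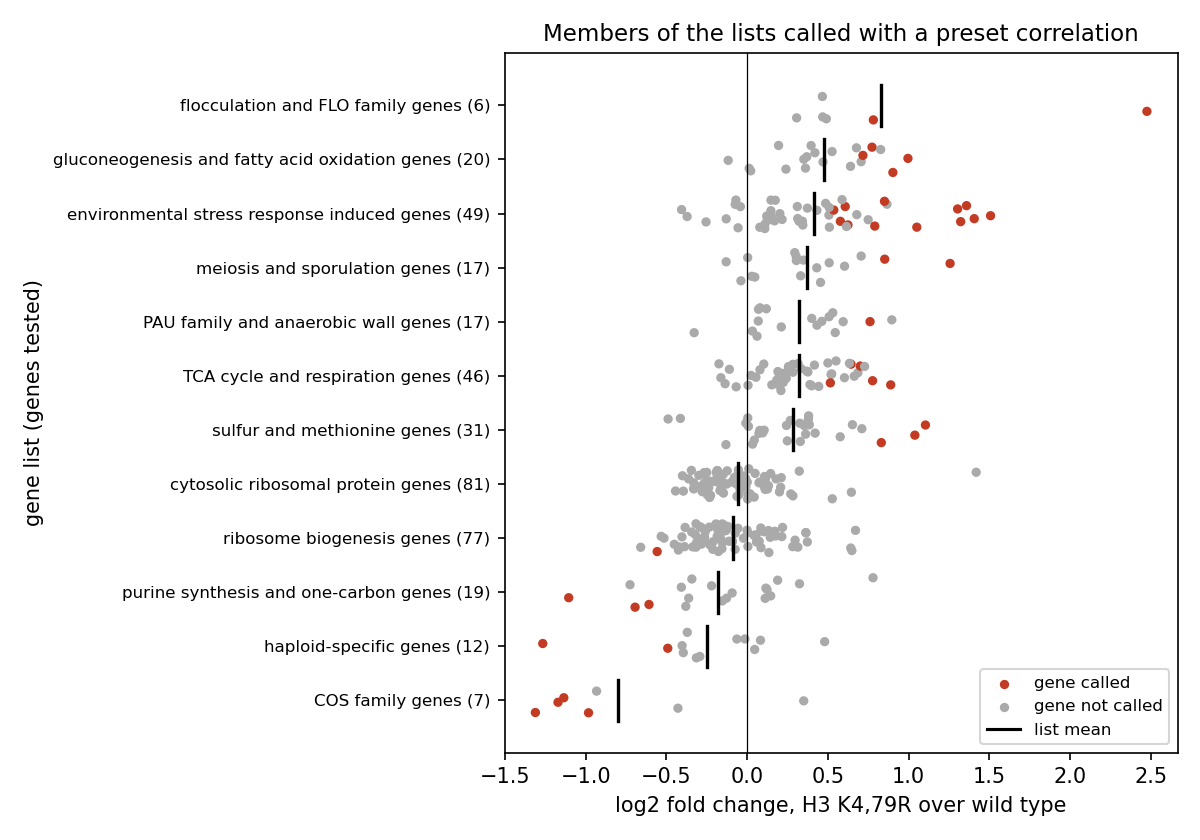
Log2 fold change, mutant over wild type, of every tested member of the 12 lists called with a preset correlation, 1 point per gene, with called genes in red, other genes in grey and the list mean as a black bar. List means run from -0.80 for the COS family to 0.83 for the flocculation genes; all 12 calls were lost with an estimated correlation.

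Of 31 sulfur and methionine genes 3 rose and none fell (6 higher and 1 lower adjusted over the list alone), with a mean of 0.28 (adjusted p = 0.00444, and adjusted p = 0.409 with an estimated correlation). STR3, a cystathionine beta-lyase gene, rose 2.15-fold, MET2 2.05-fold and the transcription factor gene MET28 1.78-fold. The list lost its call without mutant array 1 (mean 0.30, adjusted p = 0.0921) and without the lowest 40% of probe sets (mean 0.21, adjusted p = 0.0589). Of 56 genes in the amino acid biosynthesis list 6 rose and none fell, also adjusted over the list alone, without a call for the list (adjusted p = 0.427). SNO1 and SNZ1, whose products work together in vitamin B6 synthesis, rose 2.76-fold and 2.39-fold, and the arginine genes ARG7 and ARG4 rose 1.87-fold and 1.67-fold. THI4 and THI73 (1.73-fold) were the called members of 13 thiamine and vitamin B6 genes (4 higher adjusted over the list alone, list adjusted p = 0.0908). That list passed the threshold without mutant array 2 (adjusted p = 0.0133) and with fry (adjusted p = 0.0462).

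Mating-type and developmental genes moved in several directions. Among 12 haploid-specific genes HO fell and FAR1, an inhibitor of the G1 cyclin kinase, fell from 189 ± 4.58 to 134 ± 10.7 (2 lower adjusted over the list alone). The list mean was -0.25 (adjusted p = 0.0251, and adjusted p = 0.480 with an estimated correlation), and the call was lost without mutant array 2 (mean -0.30, adjusted p = 0.0577), without the lowest 40% of probe sets (mean -0.24, adjusted p = 0.0784) and with fry (adjusted p = 0.0987). Of 17 meiosis and sporulation genes 2 rose and none fell (3 and none adjusted over the list alone), SPS100 at 2.39-fold and SPS19 at 1.81-fold. Their mean was 0.37 (adjusted p = 0.0142, and adjusted p = 0.409 with an estimated correlation), with the call lost without mutant array 1 (mean 0.46, adjusted p = 0.0684). Only 17 of the 33 genes on this list were tested, most of them with low wild-type signals, between 5.10 and 52.2. None of 7 a-cell-specific genes was called, over all genes or adjusted over the list alone (list adjusted p = 0.0994). The a-factor genes read 2044 ± 375 and 1349 ± 264 for MFA2, a log2 difference of -0.60 ± 0.19, and 927 ± 226 and 582 ± 235 for MFA1.

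Of 5 alpha-cell-specific genes the alpha-factor gene MF(ALPHA)2 rose 1.59-fold between low signals, 8.40 ± 0.985 and 15.4 ± 1.01 (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.200); this list passed the threshold with fry (adjusted p = 0.0168). Of 19 pheromone response genes FIG1 rose 2.22-fold from a signal of 5.70 ± 2.52, and SST2, a regulator that dampens pheromone signalling, fell from 64.9 ± 1.19 to 30.9 ± 6.08 (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.637).

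Among 19 silencing factors no gene passed over all genes or adjusted over the list alone (list adjusted p = 0.920), with SIR2 at 0.03 ± 0.13, SIR3 at 0.10 ± 0.15, SIR4 at 0.28 ± 0.15, SAS4 at 0.46 ± 0.15 and HST2 at 0.28 ± 0.10. The small value of SIR2 turned sign with a common median, with the mutant constants divided out, without wild-type array 1 and without mutant array 1, and that of SIR3 with a common median and without mutant array 2. The median and mean of this list were above 0 while camera placed it below the other genes. In the same way none of the 19 tested genes of the list for H3 lysine 4 and 79 methylation and demethylation was called (list adjusted p = 0.639), with UBP10 at -0.47 ± 0.14 and RTF1 at 0.89 ± 0.30. The demethylase gene JHD2 and SET2, also on that list, were not tested. A probe set with shared probes, listed under the silent locus gene HMRA1, was at 0.08 ± 0.16, with a mean signal of 149 in wild type and 160 in the mutant. Its sign turned with a common median and without mutant array 1. This probe set cannot tell the silent copy from a copy at the active mating-type locus, so it does not measure silencing. The other 2 probe sets of HMRA1, with mean signals between 2.90 and 8.40, were left out by the filter. Probe sets shared by HMRA2, MATALPHA2 and HMLALPHA2 gave -0.47 (adjusted p = 0.244) and 0.41 (adjusted p = 0.317). Of those shared by MATALPHA1 and HMLALPHA1, 1 gave -0.22 (adjusted p = 0.674) and the other was left out by the filter. None of the 5 tested histone genes was called (list adjusted p = 0.975), with HTB2 at 0.27 ± 0.14 and HHO1 at 0.21 ± 0.18. Their median was -0.04 and their mean 0.04. Of the uncalled genes named here SAS4, UBP10, RTF1 and HHO1 passed the threshold without mutant array 1, and RTF1 also with a common median.

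Several other lists held 1 or more called genes without a call for the list. PHO5, the repressible acid phosphatase gene, rose 2.12-fold from 154 ± 14.95 to 329 ± 5.63 and was the only called one of 18 phosphate-responsive genes (3 higher adjusted over the list alone, list adjusted p = 0.626). HUG1, induced by DNA damage, rose 2.25-fold from 69.7 ± 6.20 to 162 ± 10.5, alone among 26 DNA damage response genes (1 adjusted over the list alone, list adjusted p = 0.504). Of 32 iron regulon genes FIT1 (1.86-fold) and HMX1 (1.56-fold) rose while ARN2, at -0.67, and FET3, at -0.51, fell (3 higher and 4 lower adjusted over the list alone, list adjusted p = 0.427). Of 15 zinc and copper genes ZRT1 rose 1.77-fold (2 higher and 2 lower adjusted over the list alone, list adjusted p = 0.728), but 1 of its 4 probe sets gave -1.03 and was called lower. That list had a median of -0.04 and a mean of 0.03. GDH3 rose 1.94-fold among 30 nitrogen catabolite genes (2 higher adjusted over the list alone, list adjusted p = 0.0908). That list passed the threshold without mutant array 2 (adjusted p = 0.0384) and with fry (adjusted p = 0.0462). ERG10 fell by 0.48 on the log2 scale among 26 ergosterol genes (none adjusted over the list alone, list adjusted p = 0.584), whose median of 0.03 and mean of -0.03 differ in sign.

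Cell cycle lists were not called. PCL1, a G1 cyclin gene, rose 1.58-fold among 33 G1/S genes (1 adjusted over the list alone, list adjusted p = 0.548). No G2/M gene of 24 was called, also adjusted over the list alone (list adjusted p = 0.548), with IQG1 at 0.65 ± 0.19 and YHP1 at 0.47 ± 0.15. PIR3 and PST1 rose among 22 M/G1 daughter-cell genes (2 higher and 1 lower adjusted over the list alone, list adjusted p = 0.562). None of 34 proteasome genes was called, also adjusted over the list alone (list adjusted p = 0.584), with RPT2 at 0.50 ± 0.13 and RPN5 at 0.79 ± 0.26. Among 8 common auxotrophic marker genes, which can differ between strains by construction, HO and ADE2 fell and HIS3 rose 1.55-fold (1 higher and 2 lower adjusted over the list alone, list adjusted p = 0.920). A second probe set of HIS3, at 0.42 on the log2 scale, was not called. The median of the markers was 0.11 and their mean -0.06.

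Position near chromosome ends was tested because silent chromatin, where H3 lacks methylation at lysines 4 and 79, lies there. Among the 10 outermost protein-coding genes of each chromosome end, 12 of 176 tested genes were called lower, or 6.82%, against 56 of 5051 genes elsewhere, or 1.11% (odds ratio 6.52, 95% interval 3.12 to 12.6, Fisher's exact p = 2.05e-06, two-sided). Higher genes were also more frequent there, 13 of 176 or 7.39% against 133 of 5051 or 2.63% (odds ratio 2.95, interval 1.498 to 5.36, exact p = 0.00116). As a list these 176 genes had a median log2 change of 0.06 and were not called by camera (adjusted p = 0.820; 27 higher and 20 lower adjusted over the list alone). The lower genes lay mainly in the 5 outermost places, where 9 of 53 genes were called lower against 3 of 123 in places 6 to 10. Fisher's exact test treats genes as independent. The 12 lower genes lay on 8 chromosome ends, some side by side, and 4 were of the COS family. The exact p-values may thus be too small and the intervals too narrow. The 6 largest changes near ends were those of FLO1, COS9, FDH1, AIF1, COS10 and COS8. FDH1, a formate dehydrogenase gene read by a probe set with shared probes, rose 2.39-fold.

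The odds ratio for lower genes missed the threshold without wild-type array 1 (5.76, exact p = 0.186) or 2 (7.16, exact p = 0.158), where 6 and 5 lower genes were called in all, and was 10.9 without wild-type array 3. It was 3.12 without mutant array 1, 7.88 without mutant array 2 and 13.0 without mutant array 3, 3.89 with the constants divided out, 3.31 with quantile normalization and 3.23 with a common median. The odds ratio for higher genes missed the threshold without wild-type array 1 (2.06) or 2 (1.79), without mutant array 1 (1.44), 2 (2.62) or 3 (3.00), and without genes read through shared probes (2.15, exact p = 0.0607).

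**Figure D3:**
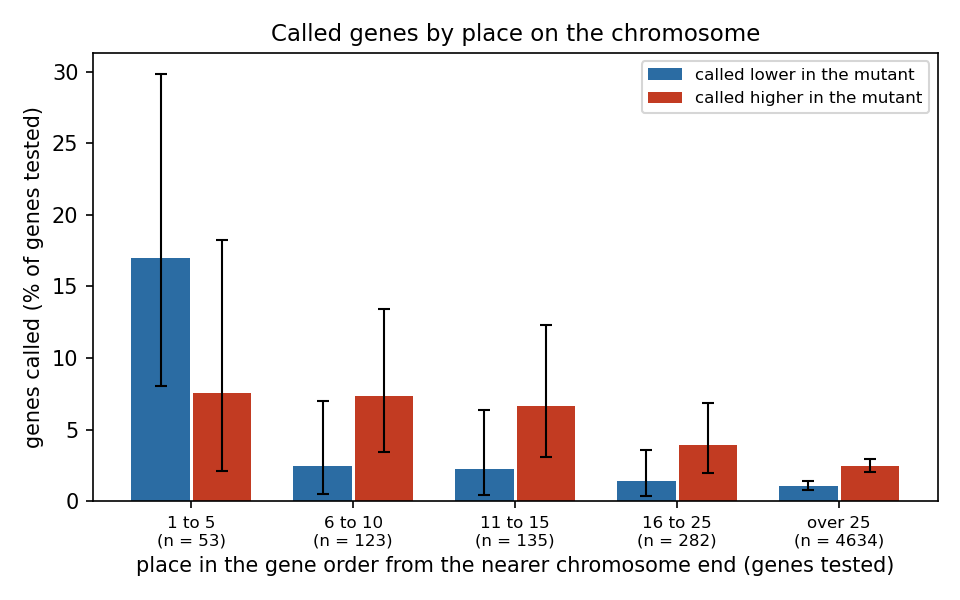
Percent of tested genes called lower (blue) and higher (red) in the mutant, by the place of the gene counted from the nearer chromosome end, with exact 95% binomial intervals as error bars and the number of genes tested under each pair of bars. The lower genes are most frequent in places 1 to 5, at 17.0% of 53 genes, and make up 1.06% of the 4634 genes beyond place 25.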

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

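The tests of shared probes near chromosome ends, of growth state, of RNA quality and of splits for chromosome ends, and the alternatives with the constants divided out (with all arrays or without mutant array 1), with the COS family left out or with 5 or 15 outermost genes, were chosen after the results were seen. The probe sets of the next paragraph were also singled out after their values were seen.

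Probe sets listed under several genes, which the tests by gene left out, carried a signal of their own: of 289 tested, 18 were called lower and 5 higher. Of the 18, 11 belong to the helicase genes of the Y′ elements (YRF1 and its relatives), repeats next to many telomeres. Of 22 tested Y′ probe sets 20 were below 0, with a median log2 change of -1.03. The probe set with the largest fall read 1131 in wild type and 427 in the mutant (log2 -1.41 ± 0.15 SE). The median was -1.08 with the constants divided out and -1.12 with a common median, with 15 called lower in each. Without 1 array in turn the median ran from -0.87 to -1.15, with 20 to 23 of the 22 or 23 tested below 0. No Y′ probe set was called without wild-type array 1 (median -1.02) or 2 (median -1.10), and 2, 13, 3 and 5 were called lower without wild-type array 3 and mutant arrays 1, 2 and 3. These probe sets share sequence and are not independent measurements. Of the other lower ones 5 belong to the COS family, 1 to PHO11 and PHO12, at -0.58 ± 0.12, while PHO5 rose, and 1 to YER190C-B and YFL068W, at -0.94. Among the 5 higher, 2 are shared by FLO1 and FLO5, 1 of them also by FLO9, at 1.16 and 0.96, 2 belong to PAU genes and 1 to DDI2 and DDI3, at 1.07.

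Of 1218 tested probe sets with no listed gene, 19 were called higher and 9 lower. A control probe set for 18S ribosomal RNA read 79.5, 74.4 and 81.3 on the wild-type arrays and 207, 336 and 236 on the mutant arrays, 3.31-fold higher in the mutant means; 4 other 18S probe sets gave between 0.848-fold and 1.65-fold. Of the 5 control probe sets for 25S ribosomal RNA, 4 were higher on every mutant array than on every wild-type array, by 0.61 to 0.68 on the log2 scale, and 1 gave 0.879-fold. The 18S probe set at 1.65-fold was also higher on every mutant array. Whether the amount of ribosomal RNA in the labelled material differed between the groups was not tested.

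The excess of lower genes near chromosome ends was weighed against 3 technical or strain explanations. Without genes read through shared probes the odds ratio was 4.78, with a lower bound of 1.80, which argues against shared probes as the whole cause; without the COS family it was 4.43. The lower genes sat on 8 different chromosome ends, which argues against the loss of 1 or 2 ends in the mutant strain. Of the 12 lower genes 5 were read through shared probes, where copies on other ends may add to the signal. The other lower genes lay on the right ends of chromosomes IV, VI and XIV and the left ends of VIII and XII. With the authors' constants divided out the odds ratio was 3.89, with a lower bound of 2.15, against 6.52 as deposited. The excess thus did not depend on the constants, although its size did. A factor common to all genes of an array does not single out genes by place, so this is a weak test. The call was lost without wild-type array 1 (5.76) or 2 (7.16), where few genes were called in all. An effect of the H3 mutation on genes next to silent chromatin stays open as a hypothesis that these 6 arrays cannot test further, as does a strain difference in repeat copies, which was not tested.

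The rise of stress response genes as a list kept its call without mutant array 1 (camera adjusted p = 3.84e-06, mean 0.49), which argues against mutant array 1 as its cause. The call also stayed with the constants divided out (adjusted p = 2.52e-07, mean 0.37). Camera compares a list with the other genes, and a constant shifts all genes of an array about alike. Dividing the constants out could therefore hardly end the call, and no conclusion on them is drawn. Over all alternatives the adjusted p of the stress list ran from 1.33e-08 with quantile normalization to 0.385 with an estimated correlation, the only one that ended its call. Cultures taken in another growth state cannot be told apart from an effect of the mutation. Both allow glucose-repressed genes to rise, and the gluconeogenesis list had a mean of 0.47, while no label gives each culture's own density. RNA quality or composition was not tested as a cause and stays open: the SPT15 3′ to 5′ ratio was 2.79 and 3.35 on mutant arrays 2 and 3, against 5.02 to 6.15 on the wild-type arrays and 5.71 on mutant array 1, and 6 of the 10 ribosomal RNA control probe sets above were higher on every mutant array than on every wild-type array.

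Leaving out mutant array 1 raised the called genes from 228 to 1120, 148 of the 150 higher and all 78 lower genes among them. With all constants divided out the count still rose 2.86-fold, from 346 to 988, which argues against its constant as the whole cause. The constants did affect the counts. Without mutant array 1, higher genes were 860 as deposited and 475 with the constants divided out, and lower genes 260 and 513. RNA or cRNA quality on that array may contribute and cannot be told apart: its ACT1 3′ to 5′ ratio of 1.00 lay outside the other 5 arrays, but its SPT15 ratio of 5.71 lay within their range.

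The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For each of 3 results only 1 of the 10 splits, the real one, reached the real value. A split that mixes the groups adds their difference to the residual spread, so few called genes are bound to result. The count near chromosome ends is a part of the called genes and adds no separate result. The real split called 228 genes and the highest other 0; it called 12 lists and the highest other 10; and it called 25 genes near chromosome ends and the highest other 0. A split that mixes the groups thus called nearly as many lists as the real one with the preset correlation.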

How the results depend on the processing

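Dividing out the constants, 5 or 15 outermost genes, leaving out the COS family, and leaving out mutant array 1 with constants divided out were chosen after seeing the data; the planned tests at 10, 20 and 30 kb were not run. No gene called in the deposited values was called in the opposite direction under any alternative fit. Counts of 150 higher and 78 lower genes became 48 and 13 at 2-fold or more and 25 and 7 at an adjusted p under 0.01; 475 and 513 with constants divided out and without mutant array 1. Lower genes became 188 and higher genes 181 (quantile normalization), 208 and 156 (common median), 164 and 182 (constants divided out), and 50 and 136 (eBayes without trend); the cause was not tested. Leaving out 1 array gave 16 to 860 higher and 5 to 260 lower genes, with fewer samples as the known difference. With the replicate number as a block, 18 higher and 6 lower genes were called. The labels do not say whether the numbers pair the samples. Residuals of same-numbered arrays correlated at -0.15, 0.07 and -0.02, which with 3 arrays per group does not settle it. The mutant constants of 0.922, 1.09 and 1.11 lay near the poly(A) control ratios of same-numbered arrays, 0.936, 1.06 and 1.08. Under the block the odds ratios near chromosome ends were 5.76 (lower, exact p = 0.186) and 1.80 (higher, exact p = 0.442), with fewer genes called. No list was called with an estimated correlation (0 higher, 0 lower), and fry called 9 higher and 1 lower, 7 of the 12 among them. Lower lists fell from 5 to 3 without the lowest 40% of probe sets, and ranged from 3 to 5 without 1 array. Odds ratios ranged from 3.12 to 13.0 (lower) and from 1.44 to 3.03 (higher) without 1 array. For higher genes the ratio missed the threshold without shared-probe sets (2.17), without genes read by them (2.15) and with 5 outermost genes (2.89). The H3 probe set at -0.86 passed the threshold with quantile normalization (-0.92), a common median (-0.96) and without mutant array 1 (-0.50; range -1.10 to -0.50); the cause was not tested. Uncalled lists changed the sign of their mean in at most 6 of 26 cases, with a common median. Low signals are limited by background and by the offset.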

Other observations

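The tests of chance and of overlapping neighbours below were chosen after the count of pairs was seen, and the pairs and genes named here were singled out after their values were seen.

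Called genes often lay beside another called gene of the same direction in the order of tested genes. There were 16 such pairs, 12 of them with neither gene among the outermost, and they include SNO1 and SNZ1, which share a divergent promoter region, FIG1 beside ATP3, and the pair PAD1 and FDC1, which act together in phenylacrylic acid decarboxylation. In 12 pairs both genes were higher and in 4 both lower. RDN5-3, a 5S ribosomal RNA gene read through shared probes (2.58-fold), and SRX1, a sulfiredoxin gene (2.34-fold), were the other genes called higher with all arrays and without each array in turn, beside the 19 named in the account of single genes.

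A hypothesis is that mRNA levels of neighbouring genes changed together. In 10000 random draws of as many higher and lower genes from the tested genes, the median number of pairs was 5 and the upper bound of the central 95% was 10, against 16 observed. Of the 16, 15 do not overlap in the reference table, against an upper bound of 10 for such pairs, which argues against shared transcripts or probes of overlapping genes as the whole cause. Without the outermost genes there were 12 pairs, against an upper bound of 8, which argues against chromosome ends alone. Functional pairs that are regulated together in any strain may account for part of the 16, and this was not tested. The count of pairs was not repeated with single arrays left out.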
